A study of Mus musculus with 12 samples.

How the data were processed

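Translating ribosome affinity purification followed by RNA sequencing (TRAP-seq) had been run on the hypothalamus and the midbrain of adult mice of the JX883 line. In this line the ribosomal protein Rpl10a fused to EGFP is expressed under the control of Slc17a6, the gene for the vesicular glutamate transporter VGLUT2, and tagged polysomes are captured with antibodies against EGFP. From each region, RNA of the immunopurified fraction (IP) and RNA of the whole tissue (input) were sequenced, with 3 libraries in each of the 4 groups, 12 libraries in all. The labels gave each library a replicate number from 1 to 3, an index and a lane. All IP libraries carried 1 index and all input libraries another, so that fraction and index cannot be separated. The IP and input of 1 region and number shared a lane, while the regions of 1 number ran on different lanes, so that region and lane cannot be separated within a number. The labels named no IP from mice without the tag.

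The deposited values were raw read counts per gene symbol, 1 table per library with 32531 gene rows. The reads had been aligned with STAR 2.0.0e to the mm10 build and counted with HTSeq, per the submitters' processing notes. These notes gave neither the annotation, nor the strand setting, nor the counting mode. The 5 summary rows of HTSeq and a row named unknown were left out of the counts. The values were whole numbers with unequal totals and had not been normalised. Total counts over genes were between 41909019 and 55148109 per library, and a count of 3, the floor used per library, came to between 0.0537 and 0.071 CPM (counts scaled by library size). Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

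Coordinates and gene types came from the GENCODE mouse release 21 annotation of the same build, matched by symbol. Of the 32531 features 23155 had a symbol there, as did 15705 of the genes tested (86.6%). Genes with near-identical copies, such as ribosomal protein, histone and haemoglobin genes, have uncertain counts, since reads with more than 1 alignment were counted separately. Genes that overlap another gene on either strand are uncertain too, because the strand setting is not known.

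Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr, which left 18128, and libraries were scaled with the trimmed mean of M values (TMM). A single fit of 4 group means over the 12 libraries, without a term for the replicate number, was tested with edgeR's robust quasi-likelihood F test. The Benjamini-Hochberg adjusted p had to lie under 0.05. The 5 comparisons were IP against input in the hypothalamus, IP against input in the midbrain, the difference between these regional effects, hypothalamus IP against midbrain IP, and hypothalamus input against midbrain input. These p-values measure the spread between these samples. CPM values are on the TMM scale and are given as mean ± SD with n = 3 libraries; whether a library holds RNA of 1 animal or of a pool is not given in the sources used here. A fold against a group with no counts in any library is a lower bound against the floor of 3 counts per library. Where the lower group held 1 to 3 counts, the ratio is given with its 95% counting interval (exact Poisson).

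The named genes were the 10 with the largest log2 fold change in each direction. They had to pass the threshold, to have a mean of at least 5 CPM in the higher group, and to have all 3 libraries of one group above all 3 of the other. For the regional difference, the CPM minimum applied to the highest of the 4 group means, and the 3 same-numbered differences of IP and input took the place of the libraries. Predicted genes with Gm or Rik symbols were replaced by the next named gene: 1 higher and 3 lower genes in the hypothalamus IP against input, 1 and 2 in the midbrain, and 1 and 1 between the IPs. Rows named only by a sequence accession were replaced too, a step decided after the data were seen: 1 higher and 29 lower in the hypothalamus and 37 lower in the midbrain. Slc17a6 and Rpl10a were named in every comparison. Results of some genes are not reported here.

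Gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives, except for those named as added. The 26 lists tested held vesicular transporters and synthetic enzymes of fast transmission, regulators and markers of subcortical glutamatergic neurons, markers of GABAergic, monoaminergic and cholinergic neurons, and general neuron markers. They also held neuropeptides, receptors of feeding and hormone signals, hypothalamic and midbrain regional transcription factors, ionotropic glutamate receptor subunits and GABA-A receptor subunits. Markers of telencephalic and striatal, thalamic, and cerebellar and hindbrain neurons stood for tissue beyond the dissection. Markers of astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, and ependymal cells, tanycytes and choroid plexus stood for other cell types, and blood cell and pituitary transcripts for blood and attached pituitary. Nuclear-retained noncoding RNAs, immediate early genes, nuclear genes of oxidative phosphorylation and cytosolic ribosomal protein genes completed them. A further list of X-inactivation and Y-linked transcripts served as a check of the libraries. The lists held 431 genes, of which 5 had no row in the tables. Up to 4 called members per list, those with the largest fold change, were examples. Members whose call ended without 1 library were left out of the text unless that library is named, a step decided after the data were seen.

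Lists were tested with camera at a preset correlation of 0.01 between genes, which compares a list with the other genes, and the p was adjusted over the lists. The same test was repeated with the correlation estimated for each list. The test fry, which asks whether the genes of a list move on balance in one direction, was run beside it. Members were counted as passing over all genes tested and also with the p adjusted over the list alone.

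The alternatives were median-of-ratios size factors in edgeR, library size only, DESeq2 1.42.0 with its Wald test, limma-voom, no filter on low counts, a filter of 1 CPM in at least 3 libraries, a fit of only the groups compared, leaving out each library in turn, and blocks by replicate. After the data were seen, fits without the 4 libraries of replicate 1, fits without the 7 structural RNA rows that held at least 0.5% of a library, and list tests without each library were added.

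Whether replicate numbers pair the libraries was checked from the data, since the labels do not say that equal numbers share an animal. Deviations from the group means were correlated between libraries of the same number across genes, and the numbers were taken to pair where every correlation exceeded 0.1. For hypothalamus IP and input, the correlations were 0.324, 0.159 and 0.155 for numbers 1 to 3, against at most 0.0383 between different numbers. For hypothalamus IP and midbrain IP they were 0.301, 0.113 and 0.219, against at most 0.019. For hypothalamus input and midbrain input they were 0.379, 0.141 and 0.167, against at most 0.0375. In these 3 comparisons the value with the block by replicate is given beside a result where it changes a call; for hypothalamus IP against input the block is the dissected tissue, unless a block by number over both regions is named.

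The procedure was first tested on simulated data. In 5 draws per comparison, with 200 genes changed among between 17665 and 17751 genes, 4-fold changes were recovered in 57.4% of genes for IP against input in each region. The share was 55.6% for the IPs, 55.4% for the inputs and 35.8% for the regional difference. For 2-fold changes the shares were 17.6%, 16.6%, 11.2%, 18.4% and 2.2% in the same order, hypothalamus first. Of the genes called, 4.57% to 6.82% had not been changed. A changed list was called in 5 of 5 draws per comparison, and at most 1 of 125 unchanged lists. Genes were drawn independently, so this rate does not cover correlated lists. Real IP against input called 6123 and 6148 genes, so the shares need not hold there.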

Results

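RNA bound to EGFP-tagged ribosomes of Slc17a6-expressing cells (IP) and RNA of the whole tissue (input) were compared in the hypothalamus and the midbrain of adult mice, with 3 libraries in each of the 4 groups. Slc17a6 encodes VGLUT2, the vesicular glutamate transporter of most subcortical excitatory neurons, so the IP is meant to sample ribosome-bound RNA of these neurons. The counts over genes in replicates 1, 2 and 3 were 55148109, 54107065 and 52869089 in the hypothalamus IP and 45931113, 47927863 and 46561103 in the hypothalamus input. They were 53625526, 52756491 and 48274691 in the midbrain IP and 52916844, 47854851 and 41909019 in the midbrain input. Between 17563 and 17974 genes had a count in an IP library and between 19747 and 20882 in an input library. The first principal component held 54.6% of the variance. Rank correlations across genes, which are not independent replicates, were 0.965 to 0.982 within a group, 0.951 to 0.974 between regions in the same fraction and 0.915 to 0.939 between fractions in the same region. The ribosomal RNA gene Rn45s took 12.3% and 12.5% of counts in the replicate 1 IPs of hypothalamus and midbrain, between 5.21% and 6.85% in the other IPs and between 2.57% and 3.97% in the inputs. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of lists from camera. Where no count adjusted over the list alone is given, it equalled the count over all genes.

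Slc17a6 (mm10, chromosome 7, 51622006 to 51671119), the gene whose regulatory sequence drives the tag, was higher in the IP of both regions. In the hypothalamus its level was 2120 ± 1230 CPM in the IP and 349 ± 154 CPM in the input (n = 3 each), a log2 fold change of 2.60 (SE 0.49, adjusted p = 0.00184). In the midbrain it was 2740 ± 1090 and 775 ± 402 CPM, a log2 fold change of 1.82 (SE 0.48, adjusted p = 0.0116). The enrichment did not differ detectably between the regions (0.78, SE 0.66, adjusted p = 0.995). In each group replicate 1 held the highest level, with 3490 CPM in the hypothalamus IP and 3950 in the midbrain IP against at most 1740 and 2390 in the other replicates. Neither the IPs (−0.37, SE 0.46, adjusted p = 0.748) nor the inputs (−1.15, SE 0.47, adjusted p = 0.35) passed between the regions. With the replicate number as a block, the level passed as lower in the hypothalamus in the IPs (−0.46, adjusted p = 0.015) and in the inputs (−1.13, adjusted p = 5.88e-05). Rpl10a (chromosome 17, 28328471 to 28331033), the gene of the ribosomal protein that is fused to EGFP in this line, was at 5.18 ± 1.43 CPM in the hypothalamus IP and 8.21 ± 0.213 in the input. In the midbrain it was at 5.53 ± 0.789 and 6.52 ± 0.324 CPM. Reads of the fusion could also count to Rpl10a. It did not pass in the hypothalamus (−0.66, SE 0.26, adjusted p = 0.0676), although it did with the block by number over both regions (−0.69, adjusted p = 0.0476), with DESeq2 (0.0181) and with limma-voom (0.0425). It did not pass in the midbrain (−0.24, adjusted p = 0.521), between the IPs (−0.09, adjusted p = 0.903), between the inputs (0.33, adjusted p = 0.784) or in the regional difference (−0.42, adjusted p = 0.999). Between the IPs its value turned to 0.11 (adjusted p = 0.848) without hypothalamus IP replicate 1.

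**Figure D1:**
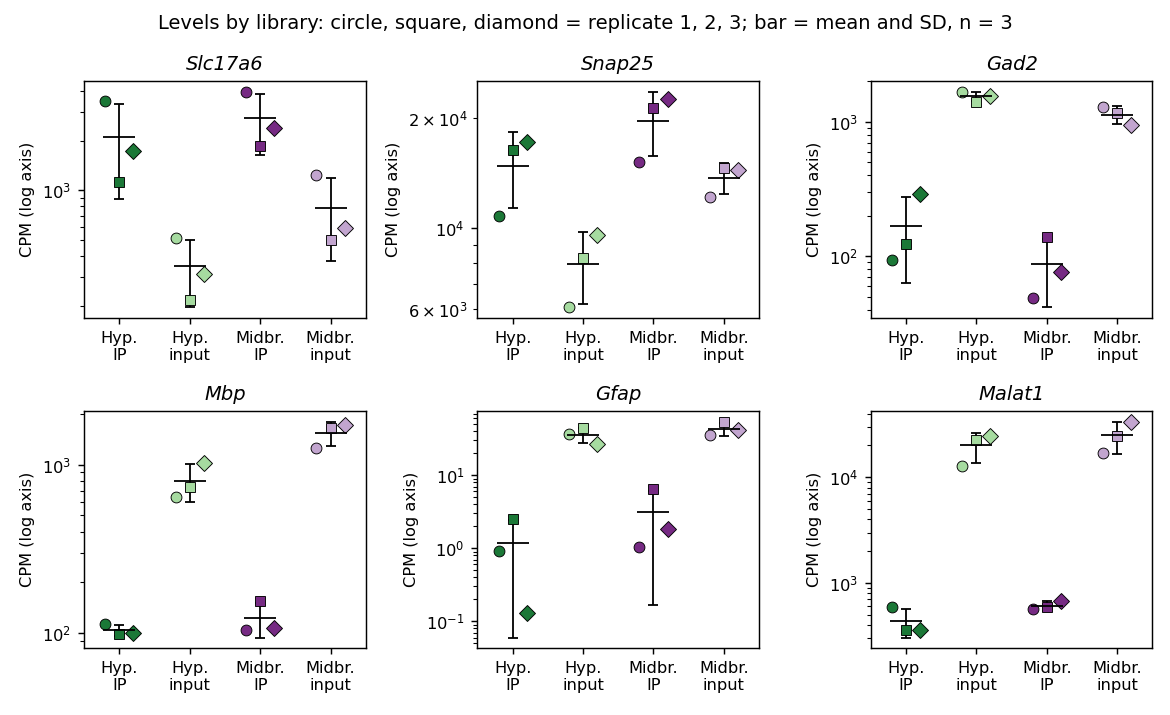
CPM of key genes (log axes) in the 12 libraries, with points for libraries and means with SD for the 4 groups. Lower error bars are cut short where the SD is close to or above the mean. Slc17a6 reaches 2120 CPM in the hypothalamus IP against 349 in the input, and 2740 against 775 in the midbrain.

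Which transcripts are held on the ribosomes of hypothalamic Slc17a6 neurons was addressed by hypothalamus IP against input. The genes with the largest increase were varied, and the fixed lists of neuropeptides and hypothalamic factors were not called (adjusted p = 0.576 and 0.377). Foxb1 (chromosome 9, 69757710 to 69760940), a forkhead factor of mammillary neurons, was at 146 ± 39.6 CPM in the IP and 14.4 ± 3.55 in the input (log2 fold change 3.34, SE 0.37, adjusted p = 6.54e-05). Gnrh1 (chromosome 14, 67745181 to 67749439), which encodes the hormone that drives gonadotropin release, was at 20.4 ± 5.44 and 2.73 ± 1.27 CPM (2.90, SE 0.42, adjusted p = 0.000628). Rprm (chromosome 2, 54084093 to 54085552), a p53-induced inhibitor of the cell cycle, led the list with 297 ± 71.7 and 26.7 ± 3.69 CPM (3.48, SE 0.26, adjusted p = 4.06e-06). Ctxn3, a small membrane protein of brain, was at 165 ± 47.5 and 18.6 ± 2.27 CPM (3.14, SE 0.40, adjusted p = 0.000147). Others were the neurexophilin gene Nxph4 (3.20), the forkhead gene Foxb2 (2.90) and 3 genes best known from striated muscle, Cox6a2 (3.10), Myh8 (2.96) and Klhl41 (2.83). Nxph4 (adjusted p = 0.0198) did not pass without hypothalamus IP replicate 1 (1.71, adjusted p = 0.11), input replicate 2 (0.0758) or input replicate 3 (0.0635).

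Of the 10 largest decreases, the G protein subunit gene Gng11 fell from 11.1 ± 4.71 CPM in the input to 0.0385 ± 0.0335 in the IP (−8.10, SE 0.82, adjusted p = 3.34e-05). Folh1, a glial glutamate carboxypeptidase, was at −7.44, Cav1, the caveolin of endothelial cells, at −6.60, Lcat, which esterifies cholesterol in astrocyte lipoproteins, at −6.49, and Laptm5, a lysosomal protein of blood-derived cells, at −6.08. Bin2 (−7.23), the ciliary dynein gene Dnali1 (−6.75), S100a6 (−6.48), Olfml1 (−6.43) and Tnfaip6 (−6.22) completed them. Their adjusted p-values lay between 1.82e-05 and 0.00133.

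Markers of every glial and vascular type tested were lower in the hypothalamus IP. Of 16 astrocyte markers 15 fell, 0 rose and 1 did not pass (15 fell adjusted over the list alone; median −4.01, camera adjusted p = 1.5e-16), among them the water channel gene Aqp4 (−5.00) and the gap junction gene Gja1 (−5.53). All 16 oligodendrocyte markers fell (16 adjusted over the list alone; median −4.70, adjusted p = 9.86e-39), with Aspa at −5.44 and Sox10 at −5.29. Of 9 precursor markers 8 fell and 1 did not pass (8 adjusted over the list alone; median −4.26, adjusted p = 6.89e-07), with Gpr17 at −4.86 and Pdgfra at −4.46. Of 15 microglia markers 14 fell and 1 did not pass (15 adjusted over the list alone; median −5.00, or −4.99 with genes absent from the IP at their bound, adjusted p = 7.8e-11). The complement genes C1qa (at least 22.2-fold lower) and C1qc (−6.35) were among them. Of 16 endothelial and mural markers 13 fell and 3 did not pass (13 adjusted over the list alone; median −3.80, or −3.58 at the bound, adjusted p = 2.02e-06), with Slco1a4 at least 31.4-fold and Cldn5 at least 8.43-fold lower. Of 15 ependymal, tanycyte and choroid plexus markers 12 fell and 3 did not pass (14 adjusted over the list alone; median −4.07, or −4.05 at the bound, adjusted p = 9.78e-05). Of 9 blood cell and pituitary transcripts 6 fell and 3 did not pass (7 adjusted over the list alone; median −4.46, adjusted p = 0.00289), with Hbb-bs at −4.46. The last call was lost with its correlation estimated (adjusted p = 0.289 with an estimated correlation). Of 10 nuclear-retained noncoding RNAs 8 fell, 1 rose and 1 did not pass (9 and 1 adjusted over the list alone; median −3.12, adjusted p = 1.51e-12). Malat1, which stays in nuclear speckles, fell from 20000 to 435 CPM (−5.52).

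Of the lists of other transmitters, that of GABAergic markers was lower in the hypothalamus IP with the preset and the estimated correlation alike. Of 19 GABAergic markers 13 fell, 0 rose and 6 did not pass (13 adjusted over the list alone; median −3.26, adjusted p = 1.19e-06), among them Lhx6 (−4.56) and Meis2 (−4.08). The genes of GABA synthesis and vesicle loading, Gad1 (−2.50), Gad2 (−3.20) and Slc32a1 (−3.78), fell within the list of 10 transporters and enzymes of fast transmission. In that list 1 rose, 4 fell and 5 did not pass (1 and 4 adjusted over the list alone; median −1.58, or −0.71 at the bound), and the list was not called (adjusted p = 0.0573). Of 13 monoaminergic markers 8 fell and 5 did not pass (9 adjusted over the list alone; median −2.21, adjusted p = 0.00587; adjusted p = 0.215 with an estimated correlation). Of 5 cholinergic markers 3 fell and 2 did not pass (3 adjusted over the list alone; median −3.84, adjusted p = 0.0573, and 0.0116 with the block by replicate). These were the acetylcholine genes Chat (−4.24), Slc18a3 (−5.38) and Slc5a7 (−3.84). Of 20 regulators and markers of subcortical glutamatergic neurons 7 rose, 1 fell and 12 did not pass (7 and 1 adjusted over the list alone; median 0.93, adjusted p = 0.00339; adjusted p = 0.149 with an estimated correlation). Besides Foxb1 and Slc17a6, Nhlh2 (2.34) and Uncx (2.12) rose. Of 15 general neuron markers 8 rose, 1 fell and 6 did not pass (10 and 1 adjusted over the list alone; median 0.60, adjusted p = 0.00587; adjusted p = 0.149 with an estimated correlation). The synaptic gene Snap25 (0.90) and the splicing factor gene Rbfox3 (0.89) rose, while Map2, whose transcript travels into dendrites, fell (−1.50). Of 22 nuclear genes of oxidative phosphorylation 15 rose, 0 fell and 7 did not pass (15 adjusted over the list alone; median 1.03, adjusted p = 3.24e-09; adjusted p = 0.149 with an estimated correlation), with Ndufa1 at 1.78 and Cox5a at 1.52.

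The other lists were not called in the hypothalamus without the block by replicate, and with it the ionotropic glutamate receptor and thalamic lists were. Of 32 neuropeptide genes 5 rose, 7 fell and 20 did not pass (5 and 8 adjusted over the list alone). Their median was −0.20 while the test pointed upward (adjusted p = 0.576). Oxt, the gene for oxytocin, fell (−3.86), as did Vip (−5.51) and the urocortin gene Ucn3 (−5.21). Of 26 receptors of feeding and hormone signals 2 rose, 3 fell and 21 did not pass (2 and 3 adjusted over the list alone; median −0.38, adjusted p = 0.761). Bdnf, whose product acts on Ntrk2, rose (1.78), and Ntrk2 fell (−1.86). Of 24 hypothalamic regional transcription factors 2 rose, 9 fell and 13 did not pass (3 and 9 adjusted over the list alone; median −0.58, adjusted p = 0.377), and of 23 midbrain factors 0 rose, 3 fell and 20 did not pass (median −0.88, or −0.64 at the bound, adjusted p = 0.223). Of 18 ionotropic glutamate receptor subunits 4 fell (2 adjusted over the list alone; median −0.57, adjusted p = 0.223, and 0.00741 with the block), and of 14 GABA-A subunits 1 rose (median −0.02, test upward, adjusted p = 0.63). Of 50 ribosomal protein genes 4 rose, 2 fell and 44 did not pass (1 and 1 adjusted over the list alone; median 0.08, adjusted p = 0.288). Of 13 telencephalic and striatal markers 2 fell (median −0.48, adjusted p = 0.394), of 10 thalamic markers 2 rose (median 1.17, adjusted p = 0.0621, and 0.000929 with the block), and of 14 immediate early genes 3 fell (0 adjusted over the list alone; median −0.11, adjusted p = 0.827). Of 6 cerebellar and hindbrain markers 1, Calb1 (1.50), rose. Their median was −0.55, or 0.30 at the bound, and the test pointed upward (adjusted p = 0.394).

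Across 18128 genes, 2576 were higher and 3547 lower in the hypothalamus IP, of which 958 and 2981 differed more than 2-fold. In 488 of the lower genes no IP library held a count. The median log2 fold change of all genes was −0.08. Scaled by library size alone, the median moved to −0.25 and the higher share of the calls from 42.1% to 28.9%, with 1632 genes higher. The 8 lists called with an estimated correlation were astrocyte (adjusted p = 0.021), oligodendrocyte (0.00542), precursor (0.019), microglia (0.0399), endothelial (0.00895), ependymal (0.0399) and GABAergic markers (0.0164) and nuclear noncoding RNAs (0.0148).

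**Figure D2:**
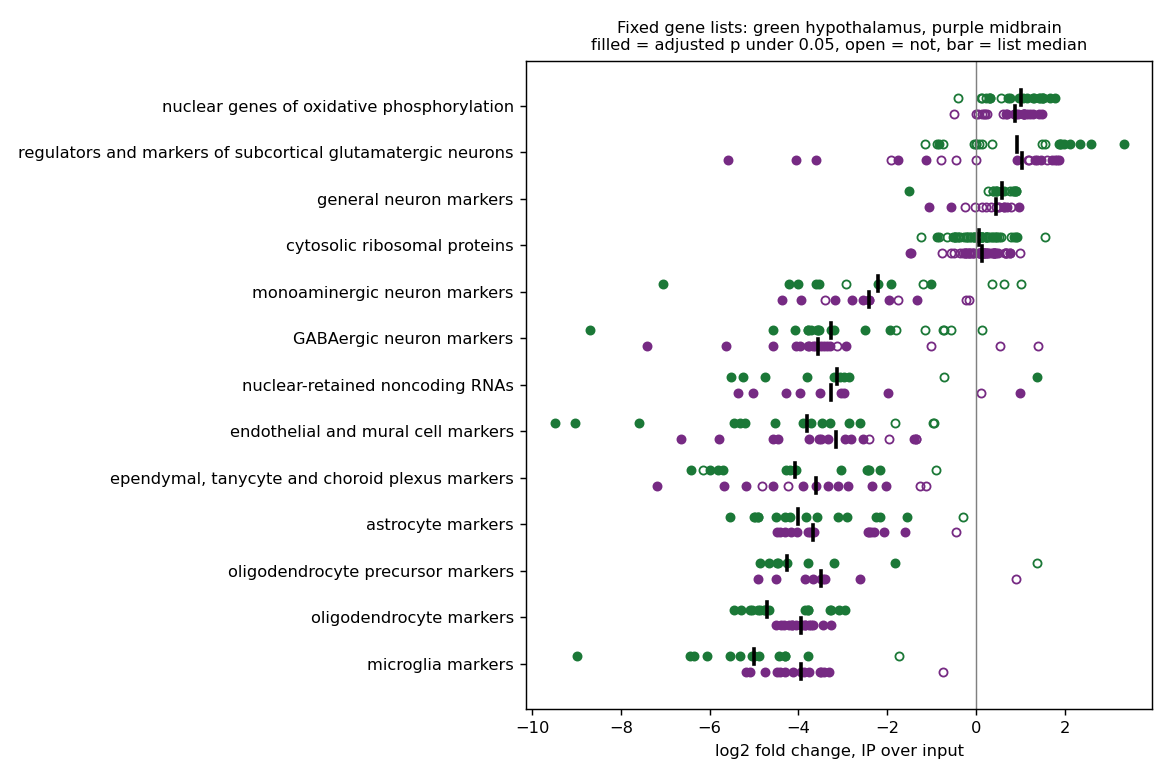
Fitted log2 fold change of IP over input for the members of the fixed gene lists, 1 point per gene, in the hypothalamus and the midbrain. The oligodendrocyte markers have a median of −4.70 and −3.93, and the nuclear genes of oxidative phosphorylation of 1.03 and 0.87.

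The same question was asked of midbrain Slc17a6 neurons by midbrain IP against input. The 10 largest increases included peptide genes, although the fixed list of neuropeptides was not called (adjusted p = 0.225). Calca (chromosome 7, 114631478 to 114636357), which encodes calcitonin and the vasodilator peptide CGRP, was at 26.9 ± 7.68 CPM in the IP and 2.92 ± 2.6 in the input (log2 fold change 3.20, SE 0.78, adjusted p = 0.00797). Grp, the gene for gastrin-releasing peptide, was at 21.1 ± 2.32 and 4.35 ± 1.43 CPM (2.28, SE 0.41, adjusted p = 0.0013). Nrgn, a postsynaptic calmodulin-binding protein, was at 324 ± 124 and 65.6 ± 30.1 CPM (2.31, SE 0.37, adjusted p = 0.000646). Fxyd7, a regulator of the neuronal sodium pump, was at 79.7 ± 22.8 and 17.2 ± 1.66 CPM (2.22, SE 0.20, adjusted p = 1.41e-05). The others were the histone gene Hist2h4 (2.94), the defensin gene Defb1 (2.78), Rprml (2.54), the oxygen-binding protein gene Ngb (2.26), Tac1 (2.31), which encodes substance P, and the neurotensin gene Nts (2.20). Tac1 (adjusted p = 0.0265) did not pass without midbrain IP replicate 1 (1.64, adjusted p = 0.109), input replicate 2 (0.0771) or input replicate 3 (0.0948). Nts (adjusted p = 0.0129) did not pass without the same libraries (0.0558, 0.0521 and 0.0536).

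The largest decreases in the midbrain IP were led by the extracellular glycoprotein gene Myoc, from 5.78 ± 2.96 CPM to 0.0468 ± 0.0281 (−6.86, SE 1.02, adjusted p = 0.000756). Klk6, a protease of oligodendrocytes, fell by 5.60 on the log2 scale (SE 0.55, adjusted p = 2.74e-05). P2ry13, a nucleotide receptor of microglia, was at −6.01, Thbd, the thrombin receptor of endothelium, at −5.44, and the transporter gene Slc6a20a at −5.83. Gdap10 (−6.14), S100a13 (−5.95), Atp13a4 (−5.84), Ranbp3l (−5.53) and Tgm2 (−5.42) completed them.

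Glial and vascular markers were lower in the midbrain IP as well. Of 16 astrocyte markers 15 fell and 1 did not pass (15 adjusted over the list alone; median −3.66, adjusted p = 2.46e-13), with Aqp4 at −4.17 and the glutamate transporter gene Slc1a3 at −4.48. All 16 oligodendrocyte markers fell (16 adjusted over the list alone; median −3.93, adjusted p = 1.26e-35), with the myelin gene Mobp at −4.20. Of 9 precursor markers 8 fell (median −3.48, adjusted p = 2.18e-06), and of 15 microglia markers 14 fell (median −3.94, adjusted p = 2.39e-08), with P2ry12 at −4.47. Of 16 endothelial and mural markers 12 fell and 4 did not pass (median −3.14, adjusted p = 2.57e-05), with Cdh5 at −5.79. Of 15 ependymal markers 11 fell and 4 did not pass (median −3.60, or −3.11 at the bound, adjusted p = 0.000172). Of 9 blood cell and pituitary transcripts 4 fell and 5 did not pass (median −4.26, or −3.83 at the bound, adjusted p = 0.00354; adjusted p = 0.284 with an estimated correlation). Of 10 nuclear noncoding RNAs 8 fell and 1 rose (median −3.27, adjusted p = 9.42e-12), with Malat1 at −5.35.

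Of 19 GABAergic markers 15 fell and 4 did not pass in the midbrain (1 rose and 16 fell adjusted over the list alone; median −3.56, adjusted p = 3.33e-07), with Six3 at −4.06. Among genes of fast transmission 1 rose, 4 fell and 5 did not pass (1 and 5 adjusted over the list alone; median −1.44, adjusted p = 0.0121; adjusted p = 0.179 with an estimated correlation), with Gad2 at −3.68, Gad1 at −3.36 and Slc32a1 at −3.29. Of 13 monoaminergic markers 9 fell and 4 did not pass (10 adjusted over the list alone; median −2.40, adjusted p = 9.03e-05; adjusted p = 0.0571 with an estimated correlation). The dopamine transporter gene Slc6a3 fell from 48.1 to 3.16 CPM (−3.93). Of 24 hypothalamic factors 12 fell and 12 did not pass (14 adjusted over the list alone; median −3.40, or −2.03 at the bound, adjusted p = 0.00162; adjusted p = 0.259 with an estimated correlation). Of 23 midbrain factors 3 rose, 12 fell and 8 did not pass (median −1.93, adjusted p = 0.0121; adjusted p = 0.357 with an estimated correlation). Those that fell included Lmx1a (−4.06), a factor of dopamine neurons, and the midbrain list was not called without midbrain IP replicate 3 (0.0954). Of 22 nuclear genes of oxidative phosphorylation 13 rose and 9 did not pass (15 adjusted over the list alone; median 0.87, adjusted p = 1.26e-06; adjusted p = 0.259 with an estimated correlation), with Ndufa1 at 1.49.

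Lists that were not called in the midbrain included the subcortical glutamatergic regulators, of which 7 rose, 5 fell and 8 did not pass. Their median was 1.05 and their mean −0.15 (adjusted p = 0.272). Of 15 general neuron markers 3 rose, 2 fell and 10 did not pass (4 and 2 adjusted over the list alone; median 0.45, adjusted p = 0.115), with Uchl1 at 0.98 and Map2 at −1.06. Of 32 neuropeptide genes 9 rose, 3 fell and 20 did not pass (median 0.07, or 0.03 at the bound, mean −0.16, test upward, adjusted p = 0.225). The corticotropin-releasing hormone gene Crh rose (3.07), while the neuropeptide Y gene Npy fell (−2.82). Of 26 receptors 5 rose, 2 fell and 19 did not pass (4 and 2 adjusted over the list alone; median 0.30, adjusted p = 0.209), with Bdnf at 1.40. Of 5 cholinergic markers 1 rose (median −0.07, mean 0.06, test upward, adjusted p = 0.657), and of 18 ionotropic glutamate receptor subunits 0 passed in edgeR (median 0.05, adjusted p = 0.525). The medians were 0.47 for GABA-A subunits (1 rose, adjusted p = 0.109), 0.15 for ribosomal protein genes (2 rose, 1 fell, 0 adjusted over the list alone, adjusted p = 0.139) and 0.74 for immediate early genes (3 rose, 1 adjusted over the list alone, adjusted p = 0.0633). They were −0.93 for telencephalic and striatal markers (1 rose, 3 fell, adjusted p = 0.668) and 0.95 for thalamic markers (1 rose, 0 adjusted over the list alone, adjusted p = 0.0603). Of 6 cerebellar and hindbrain markers 1 rose and 1 fell, and their median of −0.71 stood against an upward test (adjusted p = 0.791).

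In the midbrain 2544 genes were higher and 3604 lower in the IP, of which 865 and 3023 differed more than 2-fold. In 406 of the lower genes no IP library held a count. The 8 lists called with an estimated correlation were astrocyte (adjusted p = 0.0281), oligodendrocyte (0.001), precursor (0.0415), microglia (0.0415), endothelial (0.0161), ependymal (0.0415) and GABAergic markers (0.0106) and nuclear noncoding RNAs (0.0161).

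Whether enrichment differed between the regions was tested directly. Lhx1, a LIM homeobox factor, was at 53.1 ± 17.9 CPM in the hypothalamus IP and 11 ± 3.43 in its input, against 1.19 ± 0.706 and 7.98 ± 2.37 in the midbrain (log2 difference 5.01, SE 0.60, adjusted p = 0.00492). Its relative Lhx5 had a difference of 5.08 (SE 0.51, adjusted p = 0.0019), and Lhx1os, a noncoding neighbour of Lhx1 on the opposite strand, 5.79 (SE 0.54, adjusted p = 0.0012). Smyd1, a methyltransferase known from muscle, was at 84 ± 23.2 and 18.1 ± 4.05 CPM in the hypothalamus and at 4.12 ± 1.1 and 23.9 ± 4.14 in the midbrain (4.75, SE 0.39, adjusted p = 0.000582). Gnrh1 (9.87, SE 1.02, adjusted p = 0.00492) had no count in the midbrain IP and 0.312 ± 0.112 CPM in its input, so its difference rests on few reads and is at least 5.24 with the midbrain IP at the floor, and limma-voom did not call it (0.0543).

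The zinc finger gene Sall3 (4.98), Foxb1 (4.46) and the chaperone regulator gene Bag3 (2.93) had the same adjusted p of 0.00492. Bag3 was at 29.6 ± 7.43 and 17.8 ± 3.6 CPM in the hypothalamus and at 3.57 ± 0.406 and 16.4 ± 2.75 in the midbrain. Smaller differences were found for the potassium channel subunit gene Kcnab3 (1.71, adjusted p = 0.0483) and for Arhgef3 (1.44, adjusted p = 0.0225), besides Frmd5 (1.29, adjusted p = 0.0264), which lies outside the rule for named genes. In the other direction, the homeobox gene Meis2 was at 6.28 ± 2.63 and 107 ± 46.8 CPM in the hypothalamus and at 201 ± 107 and 138 ± 48.3 in the midbrain (−4.63, SE 0.67, adjusted p = 0.0264). The ceruloplasmin gene Cp (−4.32, adjusted p = 0.0319) and Zfp831 (−2.42, adjusted p = 0.0264) were the others. In all, 11 genes had a higher and 3 a lower enrichment in the hypothalamus. The counts were 129 and 84 in DESeq2, 8 and 0 in limma-voom and 62 and 36 with the block by tissue. The higher count was 27 without hypothalamus IP replicate 3 and between 8 and 15 without any other library. The lower count was 11 and 6 without hypothalamus IP replicates 1 and 3, 4 without midbrain IP replicate 3, and 0 or 1 without any other library. In limma-voom Sall3 (0.108), Kcnab3 (0.0863), Meis2 (0.0863), Cp (0.239) and Zfp831 (0.0649) did not pass. Without the 4 libraries of replicate 1, Sall3 (0.0806), Foxb1 (0.206), Kcnab3 (0.0806), Arhgef3 (0.132), Meis2 (0.491), Cp (0.192), Zfp831 (0.236) and Frmd5 (0.0983) did not pass. Kcnab3 did not pass without any 1 library except hypothalamus IP replicate 3 (0.0513 to 0.154). Arhgef3 did not pass without any except the hypothalamus IPs of replicates 1 and 3 and the midbrain IPs of replicates 2 and 3 (0.0526 to 0.0999). Frmd5 did not pass without any except the hypothalamus IPs of replicates 1 and 3, hypothalamus input replicate 2 and midbrain IP replicate 3 (0.0584 to 0.139), nor with library size only (0.11). Meis2 did not pass without any except hypothalamus IP replicates 1 and 3, hypothalamus input replicate 2 and midbrain IP replicate 3 (0.0504 to 0.111). Cp held only without hypothalamus IP replicate 3 and midbrain IP replicate 2 (0.0504 to 0.125 otherwise), and Zfp831 only without hypothalamus IP replicates 1 and 3 and midbrain IP replicate 3 (0.0584 to 0.111 otherwise).

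**Figure D3:**
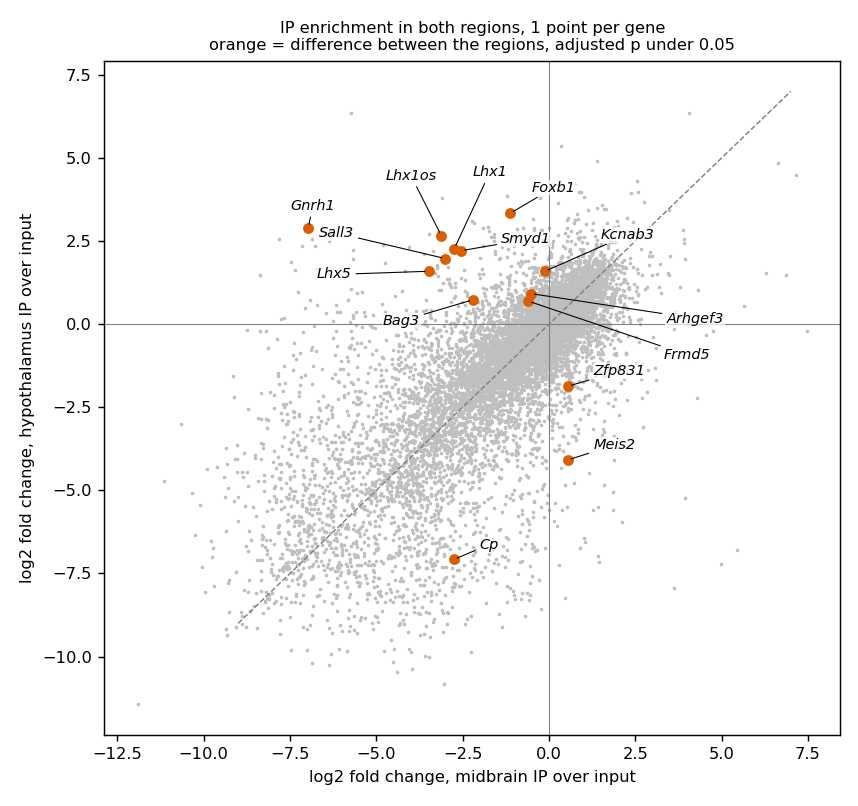
Log2 fold change of IP over input in the midbrain (horizontal axis) and the hypothalamus (vertical axis), 1 point per gene, with the 14 genes that passed the test of the difference in orange and a dashed line of equality. Smyd1, Lhx1 and Lhx5 lie above the line and Meis2 below it, and the correlation across all genes is 0.777.

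Many genes were called alike in both regions. The IPs shared 1911 higher genes, where 361.5 would be shared by independent lists, and 2635 lower genes against 705.2, and the log2 fold changes correlated with r = 0.777 across genes, which are not independent replicates. Of genes higher in the hypothalamus IP 13 were lower in the midbrain IP, and 1 was the other way. Among the lists the cholinergic markers were called and kept their call with an estimated correlation. None of the 5 members passed over all genes and 5 were lower adjusted over the list alone (median −2.93, adjusted p = 2.54e-07; adjusted p = 0.0422 with an estimated correlation), although fry did not call it (0.0616). The other 11 lists called were lost with the correlation estimated. The hypothalamic factors had a median of 2.09 (adjusted p = 3.17e-08; adjusted p = 0.106 with an estimated correlation), with 1 higher over all genes and 4 adjusted over the list alone. The subcortical glutamatergic regulators had a median of 0.79 (adjusted p = 7.39e-05; adjusted p = 0.106 with an estimated correlation), with 1 higher over all genes and 7 higher and 2 lower adjusted over the list alone.

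For immediate early genes (median −0.66, adjusted p = 0.000101) and ionotropic glutamate receptor subunits (−0.51, adjusted p = 0.000144) the adjusted p was 0.367 and 0.492 with an estimated correlation. Microglia markers (−1.01, adjusted p = 0.00212; adjusted p = 0.367 with an estimated correlation) were not called without hypothalamus input replicate 1 (0.0576). Receptors (−0.60, adjusted p = 0.00516; adjusted p = 0.492 with an estimated correlation) were not called without hypothalamus input replicate 1, hypothalamus IP replicate 2, midbrain IP replicate 1 or midbrain input replicate 2 (0.0558 to 0.202). Astrocyte markers (−0.62, adjusted p = 0.0104; adjusted p = 0.48 with an estimated correlation) were not called without hypothalamus input replicate 1 (0.202) or midbrain IP replicate 2 (0.0536). Oligodendrocyte markers (−0.55, adjusted p = 0.0256; adjusted p = 0.48 with an estimated correlation) were not called without hypothalamus IP replicate 2, hypothalamus input replicate 3, midbrain IP replicate 2 or midbrain input replicate 1 (0.0559 to 0.405). Midbrain factors (median 1.69, mean 0.19, adjusted p = 0.0256; adjusted p = 0.48 with an estimated correlation) were not called without hypothalamus input replicate 3, midbrain IP replicate 3 or midbrain input replicate 2 (0.0751 to 0.294). General neuron markers (0.14, adjusted p = 0.041; adjusted p = 0.478 with an estimated correlation) were called only without hypothalamus IP replicate 1, hypothalamus input replicate 3, midbrain input replicate 1 and midbrain IP replicate 3 (0.0551 to 0.198 otherwise). GABA-A subunits (−0.17, adjusted p = 0.041; adjusted p = 0.693 with an estimated correlation) were not called without hypothalamus input replicate 1, hypothalamus IP replicates 2 and 3, midbrain IP replicate 1 or midbrain input replicates 2 and 3 (0.0747 to 0.782). The 14 remaining lists were not called. Their adjusted p-values were 0.0571 for genes of oxidative phosphorylation (median 0.18), 0.0598 for endothelial markers (−1.17), 0.0685 for monoaminergic markers (0.38) and 0.198 for GABAergic markers (0.48, 1 lower). They were 0.362 for neuropeptides (−0.13, 1 higher), precursor markers (median 0.25, mean −0.13) and telencephalic markers (median −0.26, mean 0.02), 0.444 for genes of fast transmission and 0.505 for nuclear noncoding RNAs (−0.17). They were 0.589 for ribosomal protein genes (−0.07), 0.678 for cerebellar markers (0.41), 0.813 for blood cell and pituitary transcripts (−0.06), 0.966 for thalamic markers (0.04) and 0.979 for ependymal markers (−0.14). Adjusted over the list alone, these lists held 3 higher and 2 lower GABAergic markers, 3 and 1 monoaminergic markers, 4 and 5 neuropeptide genes, 2 lower endothelial markers, 1 higher ependymal marker and 1 lower telencephalic marker. Among the lists called above, 7 and 5 midbrain factors, 2 higher general neuron markers, 1 lower oligodendrocyte marker and 2 lower immediate early genes passed so.

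Hypothalamus IP against midbrain IP compared the RNA of the IPs between the regions. This comparison does not remove tissue RNA carried over into an IP, so a gene named here need not come from Slc17a6 neurons. The 10 largest increases included peptide and regulator genes of the hypothalamus. Hcrt, which encodes the arousal peptides called orexins, was at 68.8 ± 32.9 CPM in the hypothalamus IP and 0.0693 ± 0.034 in the midbrain IP (log2 fold change 9.92, SE 0.75, adjusted p = 3.67e-05). Pmch, the gene for melanin-concentrating hormone, was at 181 ± 88.9 and 0.863 ± 0.866 CPM (7.71, SE 0.94, adjusted p = 0.000823), and Trh, for thyrotropin-releasing hormone, at 25.3 ± 16.8 and 0.0384 ± 0.0665 CPM (9.20, SE 1.16, adjusted p = 0.00107). Nkx2-1, the homeobox factor of the ventral hypothalamus, was at 193 ± 73.6 and 0.0353 ± 0.044 CPM (12.36, SE 1.17, adjusted p = 0.000162). Gnrh1, at 20.4 ± 5.44 CPM in the hypothalamus IP, was at least 331-fold higher than in the midbrain IP, where no library held a count (adjusted p = 3.67e-05). Fezf1 was at least 293-fold higher (adjusted p = 0.000191), Foxb2 at least 165-fold (0.000316) and Tbx3 at least 136-fold (0.00231, and 0.0583 in limma-voom). The homeobox genes Bsx (7.42) and Isl1 (6.92) were also among the 10.

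The 10 genes with the largest change toward the midbrain IP included transcription factors. Tfap2d, an AP-2 factor, was at 55.9 ± 32.9 CPM and at least 977-fold higher than in the hypothalamus IP, where it had no count (adjusted p = 0.000578, and 0.0618 without the 4 libraries of replicate 1). Pou4f2, a POU factor of visual neurons, was at 49.7 ± 20.6 CPM and at least 868-fold higher (adjusted p = 0.00067). Its relative Pou4f1 was at −7.13 (SE 0.82, adjusted p = 0.000622), Tfap2b at −5.13 (SE 0.47, adjusted p = 0.000135) and Meis2 at −5.00 (SE 0.54, adjusted p = 0.000387). The Iroquois genes Irx1 (−6.11) and Irx2 (−5.53) did not pass with only the groups compared in the fit (0.0677 and 0.0952). Barhl1 (−5.11), Serpina3g (−4.88) and Bnc2 (−4.34) completed the 10.

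Of 24 hypothalamic factors 17 were higher in the hypothalamus IP, 0 lower and 7 did not pass (20 adjusted over the list alone; median 7.56, or 4.32 at the bound, adjusted p = 4.34e-45), with Hmx2 at least 55.5-fold higher. Against the hypothalamus input, 2 of these factors rose and 9 fell in the hypothalamus IP. Of 23 midbrain factors 10 were lower, 5 higher and 8 did not pass (14 and 5 adjusted over the list alone; median −3.61, or −3.33 at the bound, adjusted p = 7.94e-10; adjusted p = 0.09 with an estimated correlation). En1 (−6.11) and En2 (at least 79.9-fold lower), the engrailed factors of the midbrain-hindbrain boundary, were lower. The 5 higher members were Lmx1b (6.15), Foxa2 (5.58), Lmx1a (5.44), Foxa1 (3.53) and Nr4a2 (2.04), known from dopamine neurons and, for the Lmx1 and Foxa genes, from the posterior hypothalamus. The first 4 were named after their values were seen. Of 20 subcortical glutamatergic regulators 11 were higher, 4 lower and 5 did not pass (12 and 6 adjusted over the list alone; median 1.32, adjusted p = 5.06e-07). Of 32 neuropeptide genes 10 were higher, 4 lower and 18 did not pass (15 and 6 adjusted over the list alone; median 1.81, adjusted p = 5.22e-09; adjusted p = 0.14 with an estimated correlation). Of 19 GABAergic markers 6 were higher, 3 lower and 10 did not pass (11 and 4 adjusted over the list alone; median 1.16, adjusted p = 0.00242; adjusted p = 0.09 with an estimated correlation). Of 26 receptors 2 were higher, the bombesin receptor gene Brs3 (at least 51.6-fold) and the cholecystokinin receptor gene Cckar (2.59), and 24 did not pass (3 higher and 1 lower adjusted over the list alone; median 0.06, adjusted p = 0.159).

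Among the lists of glial and vascular cells, only the oligodendrocyte markers were called as lower in the hypothalamus IP with the preset and the estimated correlation alike. Of these 16 markers 7 were lower and 9 did not pass (11 adjusted over the list alone; median −1.50, adjusted p = 4.42e-16, and 0.0367 with an estimated correlation), with the myelin gene Mal at −1.84. Of 16 astrocyte markers 2 were lower (4 adjusted over the list alone; median −0.58, adjusted p = 0.000157; adjusted p = 0.214 with an estimated correlation), with S100b at −2.42. Of 15 microglia markers 1 was lower (2 adjusted over the list alone; median −1.45, or −1.18 at the bound, adjusted p = 0.000128; adjusted p = 0.141 with an estimated correlation). Of 16 endothelial and mural markers 3 were lower (median −1.40, or −1.08 at the bound, adjusted p = 0.0102; adjusted p = 0.09 with an estimated correlation and 0.071 with the block by replicate number). Precursor markers (1 of 9 lower, 2 adjusted over the list alone; median −0.24, adjusted p = 0.0414; adjusted p = 0.354 with an estimated correlation, 0.0945 with the block) were not called without hypothalamus IP replicate 2 (0.436, median 0.21), midbrain IP replicate 2 (0.075), hypothalamus IP replicate 3 (0.0603) or midbrain IP replicate 3 (0.139). Cholinergic markers (0 of 5, 3 adjusted over the list alone; median −2.12, adjusted p = 0.0414; adjusted p = 0.214 with an estimated correlation, 0.124 with the block) were not called without midbrain IP replicate 1 (0.071), hypothalamus IP replicate 2 (0.126) or midbrain IP replicate 2 (0.0705). Of 18 ionotropic glutamate receptor subunits 2 were lower (4 adjusted over the list alone; median −0.74, adjusted p = 3.81e-05; adjusted p = 0.449 with an estimated correlation). Of 10 thalamic markers 0 passed over all genes and 7 were lower adjusted over the list alone (median −1.55, adjusted p = 9.07e-05; adjusted p = 0.354 with an estimated correlation).

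The other lists were not called between the IPs. The medians were −0.75 for monoaminergic markers (2 higher, 1 lower, 4 and 4 adjusted over the list alone, adjusted p = 0.682), 0.01 for general neuron markers (0 passed, mean −0.14, adjusted p = 0.413), −0.30 for genes of fast transmission (1 lower, adjusted p = 0.479) and −0.22 for telencephalic markers (2 higher, 2 lower, 4 and 2 adjusted over the list alone, mean 0.38, adjusted p = 0.729). Among the last, the cortical factor gene Tbr1 was higher (4.04). They were −0.01 for ependymal markers (adjusted p = 0.879), 2.12 for blood cell and pituitary transcripts (0 passed, 1 lower adjusted over the list alone, adjusted p = 0.224), −0.11 for nuclear noncoding RNAs (1 lower, adjusted p = 0.219) and 0.39 for immediate early genes (0 passed, 2 higher and 1 lower adjusted over the list alone, adjusted p = 0.368). For genes of oxidative phosphorylation the median was −0.01 (adjusted p = 0.905), for ribosomal protein genes 0.17 (adjusted p = 0.0914) and for GABA-A subunits −0.11 (adjusted p = 0.479). Of 6 cerebellar and hindbrain markers Calb1 was higher (1.28), and the list's median of −0.23 stood against an upward test (adjusted p = 0.479).

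In all, 372 genes were higher and 401 lower in the hypothalamus IP than in the midbrain IP. With the block by replicate number the counts were 800 and 1224, in DESeq2 848 and 952, and with only the groups compared in the fit 112 and 84. They fell to 230 and 221 without midbrain IP replicate 1, to 199 and 174 without hypothalamus IP replicate 2 and to 232 and 242 without midbrain IP replicate 2. The 3 lists called with an estimated correlation were the hypothalamic factors (adjusted p = 0.00244), the oligodendrocyte markers (0.0367) and the subcortical glutamatergic regulators (0.046).

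**Figure D4:**
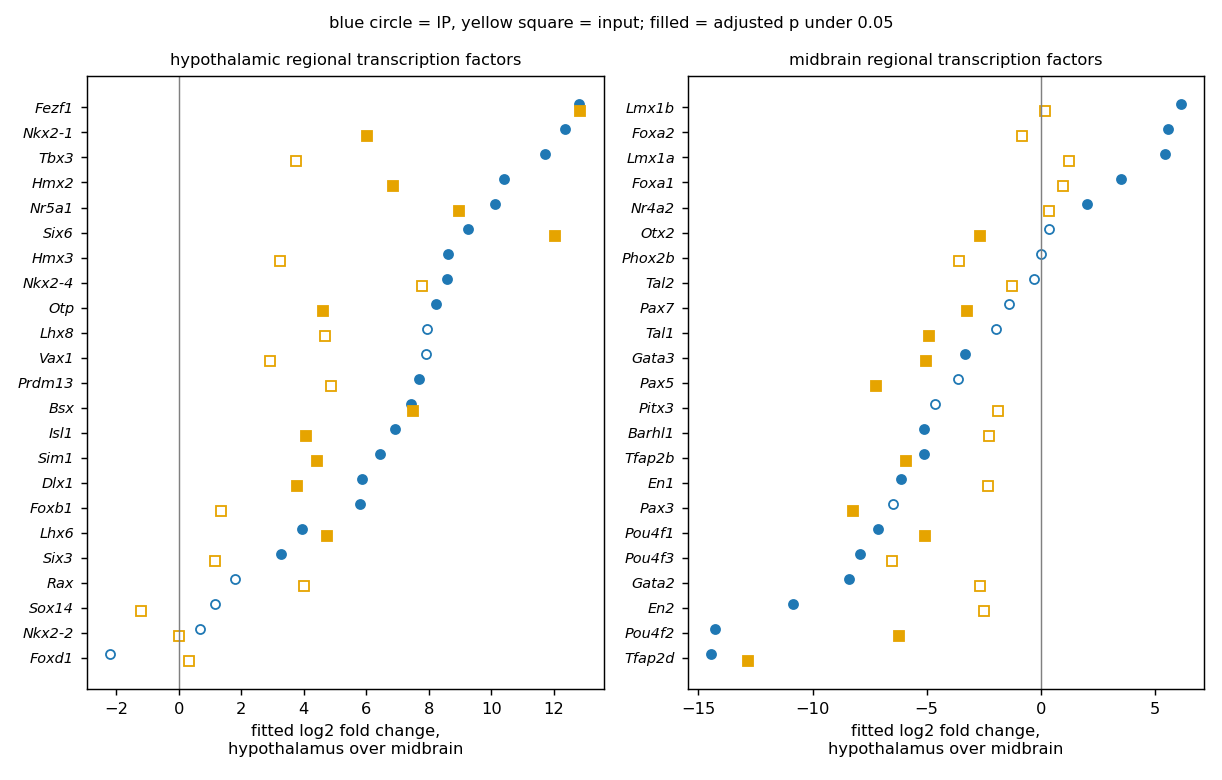
Fitted log2 fold change of hypothalamus over midbrain for the hypothalamic and midbrain regional transcription factors, 1 point per gene shown, in the IPs and in the inputs. As whole lists the hypothalamic factors have a median of 7.56 in the IPs and 4.24 in the inputs, and the midbrain factors of −3.61 and −2.64.

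The inputs show how the dissected tissues differed without purification. The 10 largest differences toward the hypothalamus included peptide genes and transcription factors. Oxt was at 45 ± 19.6 CPM in the hypothalamus input and 0.0852 ± 0.131 in the midbrain input (log2 fold change 9.10, SE 0.92, adjusted p = 0.000587), and Hcrt at 130 ± 45.8 and 0.918 ± 0.698 CPM (7.16, SE 0.61, adjusted p = 0.00022). Avp, the vasopressin gene, was at 8.86 (adjusted p = 0.00814, and 0.0727 in limma-voom), Trh at 7.12, Pmch at 5.61 and Nkx2-1 at 6.01. Fezf1, at 18.4 ± 6.03 CPM, was at least 290-fold higher (adjusted p = 0.000539), the eye and pituitary factor Six6 at least 165-fold (0.00303), and the retinoic acid binding protein gene Crabp1 was at 5.54. The GABAergic factor Dlx2 (4.87, adjusted p = 0.0259) did not pass without hypothalamus input replicate 1, 2 or 3 or midbrain input replicate 1 or 2 (0.0686 to 0.122).

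In the midbrain input Tfap2d was at least 312-fold higher (adjusted p = 0.00218), Tfap2b was at −5.92 (SE 0.49, adjusted p = 2e-04), Pou4f2 at −6.21 (adjusted p = 0.00844) and Pou4f1 at −5.07 (adjusted p = 0.00592). The GABAergic selector gene Tal1 was at −4.88 (SE 0.58, adjusted p = 0.00147), the potassium channel gene Kcng4 at −3.39 and Bnc2 at −3.16. The serotonin synthesis gene Tph2 (−5.61, adjusted p = 0.0231) did not pass without hypothalamus input replicate 1, 2 or 3 or midbrain input replicate 2 or 3 (0.0691 to 0.126). Gata3 (−5.02, adjusted p = 0.0105) did not pass without hypothalamus input replicate 2 (0.0711) or midbrain input replicate 2 (0.0524). Pax7 (−3.25, adjusted p = 0.0498) passed only without hypothalamus input replicate 2 (0.0986 to 0.169 without another library). Without the 4 libraries of replicate 1, Avp, Nkx2-1, Pmch, Tfap2d, Pou4f2, Pou4f1, Dlx2, Gata3 and Pax7 did not pass (0.0576 to 0.209).

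Of 24 hypothalamic factors 11 were higher in the hypothalamus input and 13 did not pass (20 adjusted over the list alone; median 4.24, or 4.03 at the bound, adjusted p = 1.26e-45). Of 23 midbrain factors 10 were lower and 13 did not pass (15 adjusted over the list alone; median −2.64, adjusted p = 7.56e-31). Of 32 neuropeptide genes 11 were higher, 1 lower and 20 did not pass (17 and 3 adjusted over the list alone; median 2.49, adjusted p = 8.49e-21). Of 16 oligodendrocyte markers 3 were lower and 13 did not pass (11 adjusted over the list alone; median −0.95, adjusted p = 4.98e-15). These 4 lists were called with an estimated correlation too (adjusted p = 0.00159, 0.00909, 0.0421 and 0.0191 in this order). Of 26 receptors 5 were higher (7 adjusted over the list alone; median 0.41, adjusted p = 7.89e-08; adjusted p = 0.175 with an estimated correlation), with Brs3 at 7.14 and Cckar at 3.16. Of 15 general neuron markers 3 were lower (1 higher and 4 lower adjusted over the list alone; median −0.24, adjusted p = 0.000401; adjusted p = 0.0857 with an estimated correlation), with the neurofilament genes Nefh at −1.46 and Nefl at −0.98. Of 19 GABAergic markers 5 were higher and 2 lower (9 and 3 adjusted over the list alone; median 0.62, adjusted p = 0.00188; adjusted p = 0.0636 with an estimated correlation). Of 14 immediate early genes 2 were higher (9 adjusted over the list alone; median 0.94, adjusted p = 4.63e-09; adjusted p = 0.0857 with an estimated correlation).

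Monoaminergic markers were lower as a list (0 higher and 1 lower, 1 and 4 adjusted over the list alone; median −1.43, adjusted p = 0.00183; adjusted p = 0.138 with an estimated correlation) and cholinergic markers higher (1 of 5; median 1.43, adjusted p = 0.00254; adjusted p = 0.0857 with an estimated correlation). Of 10 thalamic markers 0 passed over all genes and 5 were lower adjusted over the list alone (median −1.33, adjusted p = 3.4e-07; adjusted p = 0.18 with an estimated correlation). The subcortical glutamatergic regulators (5 higher, 1 lower, 6 and 4 adjusted over the list alone; median 0.24, adjusted p = 0.0142; adjusted p = 0.193 with an estimated correlation) were not called without midbrain input replicate 3 (0.0803). Genes of fast transmission (0 passed, 2 adjusted over the list alone; median −0.07, adjusted p = 0.0265; adjusted p = 0.178 with an estimated correlation) were not called without midbrain input replicate 1 (0.101) or hypothalamus input replicate 2 (0.224). Genes of oxidative phosphorylation (median −0.21, adjusted p = 0.0182; adjusted p = 0.517 with an estimated correlation) were not called without hypothalamus input replicate 1 (0.484) or midbrain input replicate 2 (0.237). Ribosomal protein genes (median 0.23, adjusted p = 0.00309; adjusted p = 0.517 with an estimated correlation) were not called without midbrain input replicate 1 (0.162), hypothalamus input replicate 2 (0.0754) or hypothalamus input replicate 3 (0.0568). The lists not called were astrocyte (adjusted p = 0.0808, and 0.0312 with the block by replicate number), precursor (0.103), microglia (0.0794), endothelial (0.0938), ependymal (0.77, median 0.82, mean −0.20), telencephalic (0.0541, 1 higher, 3 higher and 1 lower adjusted over the list alone), and cerebellar and hindbrain markers (0.568, 1 higher, 1 and 1 adjusted over the list alone). Blood cell and pituitary transcripts (0.0509, and 0.0105 with the block, 3 higher adjusted over the list alone), nuclear noncoding RNAs (0.383), ionotropic glutamate receptor subunits (0.383) and GABA-A subunits (0.211, 1 higher, 2 adjusted over the list alone) were not called either. Otx2, a member of both the midbrain factor list and the ependymal, tanycyte and choroid plexus list, was lower (−2.64), and Calb1 was higher (1.32).

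In all, 182 genes were higher and 109 lower in the hypothalamus input, 521 and 576 with the block by replicate number, and 437 and 340 in DESeq2. The lower count was 173 in limma-voom and 204 with only the groups compared in the fit. Scaled by library size alone, the median of all genes moved from 0.01 to 0.14 and the higher share of the calls from 62.5% to 74.1%. Without any 1 of the 6 input libraries the higher count lay between 65 and 108, and the lower count between 28 and 55 without any except hypothalamus input replicate 3. The comparisons of the IPs and of the inputs shared 102 higher genes, where 3.735 would be shared by independent lists, and 63 lower genes against 2.411, and their log2 fold changes correlated with r = 0.421 across genes, which are not independent replicates.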

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

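The tests of carry-over, scaling, loss of non-neuronal RNA and skeletal muscle RNA were chosen only after the result was seen. That of transcript length, GC content and expression level was chosen before.

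A regional difference in the enrichment over input marked 14 genes: Lhx1os (5.79), Lhx5 (5.08), Lhx1 (5.01), Sall3 (4.98), Smyd1 (4.75), Foxb1 (4.46), Bag3 (2.93), Kcnab3 (1.71), Arhgef3 (1.44), Frmd5 (1.29) and Gnrh1 (fitted 9.87, at least 5.24 with the midbrain IP at the floor) with a higher, and Zfp831 (−2.42), Cp (−4.32) and Meis2 (−4.63) with a lower log2 enrichment in the hypothalamus. Unequal carry-over of input RNA into the IP pulls a fold change toward 0 and cannot turn its sign, yet 10 of the 11 higher genes passed as higher in the hypothalamus IP and lower in the midbrain IP, which argues against it as the whole cause. The smallest of the 11 differences, 1.29, argues against scaling, which moved the median of all genes to −0.10 at most. With library size only, Frmd5 (1.20, SE 0.24, from 1.29, SE 0.19) and Arhgef3 (1.36, SE 0.23, from 1.44, SE 0.20) did not pass (0.11 and 0.0514). A difference between the regions themselves remains open and untested: the 11 genes may mark untagged cells in the midbrain and tagged ones in the hypothalamus.

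Nuclear genes of oxidative phosphorylation were called as higher in both IPs with the preset correlation, with 15 and 13 of 22 members past the threshold in the hypothalamus and midbrain, but not with an estimated correlation (adjusted p = 0.149 and 0.259). Random lists, 10000 per region, were matched on transcript length, GC content and mean expression. In the hypothalamus 3.38% had a median as high as the observed 1.03 (random median 0.82), in the midbrain 17.8% as high as 0.87. Genes were drawn independently but list members were correlated (estimated at 0.427 and 0.447), so this cannot decide. These properties stay open and may account for much of the rise. Loss of RNA of non-neuronal cells stays open, because the median exceeded that of the general neuron markers by 0.42 in the hypothalamus (permutation p = 0.0648, 2-sided, across genes, which are not independent replicates) and by 0.43 in the midbrain (0.0735). Ribosomal protein transcripts, which are short as well, had medians of only 0.08 and 0.15, and a higher share of these mRNAs on ribosomes of Slc17a6 neurons was not tested.

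Genes best known from striated muscle were higher in the hypothalamus IP: Myh8 (2.96), Klhl41 (2.83), Cox6a2 (3.10), Smyd1 (2.21), Hspb3 (3.16), Myh2 (3.17) and Tcap (ratio 95, 95% counting interval 26.3 to 784, with 2 reads in the input), a group picked after the values were seen. RNA of skeletal muscle in the dissected tissue would bring Ckm, among the most abundant muscle transcripts, above Myh8, but the highest ratio of Ckm to Myh8 in a hypothalamus IP library was 1.1%. Ckm (0.135 CPM), Mylpf (0.265), Tnnt3 (0.00612) and Tnni2 (0) stayed low. But Acta1 (6.63 CPM) was higher in the hypothalamus IP (1.28, adjusted p = 0.015), Mb was at 1.09 CPM and Atp2a1 at 0.527. In the midbrain IP Myh8 was higher (2.01, adjusted p = 0.0346) and Smyd1 lower (−2.54, adjusted p = 5.81e-05). Klhl41 (−0.19), Hspb3 (−0.47), Myh2 (0.84), Cox6a2 (1.98) and Tcap did not pass. Only Smyd1 passed in the regional difference. Expression of the group in Slc17a6 neurons stays open, with no other test.

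In the list test the cholinergic markers had a lower enrichment in the hypothalamus than in the midbrain (median log2 difference −2.93). The share of reads with more than 1 alignment, a summary row outside the gene counts, was 37.3% or more in every IP library and at most 30.0% in every input library.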

How the results depend on the processing

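The fits without the 4 libraries of replicate 1, those without the structural RNA rows, and the list tests without 1 library were chosen only after the result was seen. Over all settings, 4 of 12 counts of genes stayed within the limit for an unchanged count, 216 of 327 named genes and list examples kept their direction and side of the threshold, and 23 of 67 called lists did. An estimated correlation ended 43 of the 67 list calls and fry 22. With library size only, 1632 genes were higher in the hypothalamus IP and 1244 in both IPs. DESeq2 gave 848 higher and 952 lower genes between the IPs, 437 and 340 between the inputs and 129 and 84 for the regional difference, and it left 26 genes, or 1428 between the inputs, without an adjusted p. Limma-voom gave 173 lower genes between the inputs, and 8 higher and 0 lower for the regional difference, where 1190 genes had an unadjusted p under 0.05 in edgeR. Without a filter on low counts the regional difference had 17 higher genes. With only the groups compared, the IPs had 112 higher and 84 lower genes and the inputs 204 lower genes. Without the 4 libraries of replicate 1, and so with fewer samples, the IPs had 562 lower genes and the regional difference 7 higher genes. For the settings before that the cause was not tested.

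Without 1 library at a time, with fewer samples, the counts between the IPs ranged from 199 to 387 higher and from 174 to 440 lower. Those between the inputs ranged from 65 to 108 higher and from 28 to 82 lower, and those of the regional difference from 8 to 27 higher and from 0 to 11 lower. Rpl10a between the IPs ranged from −0.26 to 0.11 and turned its sign without hypothalamus IP replicate 1, and the cause was not tested. Where a group kept 2 libraries, they were assumed to vary like the other groups. The inputs without the 4 libraries of replicate 1 had 136 higher and 150 lower genes.

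With the replicate block by number, 800 genes were higher and 1224 lower between the IPs, 521 and 576 between the inputs, 58 and 47 for the regional difference and 3672 and 4280 in midbrain IP against input; the cause of the larger counts was not tested. With the block by dissected tissue the counts were 3504 and 3905 in the midbrain and 62 and 36 for the regional difference. In the midbrain the replicate numbers were not taken as a pairing of IP and input, since the correlations of same-numbered libraries were 0.189, 0.0754 and 0.157, although every library correlated best with its own number and other numbers reached at most −0.0252. Under the block the calls of Fau (0.0793) and Egr2 (0.0893) in the hypothalamus and of Rpl9 (0.0533), Rps2 (0.0626), Kcnj8 (0.0836) and Hdc (0.0748) in the midbrain ended. In the regional difference those of the midbrain factors (0.185 by tissue and 0.0845 by number) and the oligodendrocyte markers (0.1) ended. Some lists were called only under a block. In the midbrain these were the subcortical glutamatergic regulators (0.0116 by tissue, not by number at 0.0624), general neuron markers (0.0284, not by number at 0.0627), immediate early genes (0.024, not by number at 0.0515), GABA-A subunits (0.00423 and 0.0114) and thalamic markers (0.000123 and 0.00776). In the regional difference they were genes of oxidative phosphorylation (0.00785 and 0.01) and, by number alone, monoaminergic markers (0.0434, against 0.237 by tissue). Among the named genes, list examples and 26 lists, the block changed no other call than these and those given beside Slc17a6, Rpl10a and the lists in the hypothalamus, between the IPs and between the inputs.

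Of 63 list tests not called, 25 were called without 1 library, and the cause was not tested. In the hypothalamus these were genes of fast transmission (0.0412 without IP replicate 1, 0.00686 without input replicate 2), cholinergic markers (0.0412 and 0.0117 without the same), ionotropic glutamate receptors (0.00338, IP 1), ribosomal protein genes (0.0412, IP 1) and thalamic markers (0.00714, 0.0153 and 0.00626; IP 1, IP 2 and input 3). In the midbrain they were general neuron markers (0.0477, IP 1), GABA-A subunits (0.0151, input 1), thalamic markers (0.0266, 0.0174 and 0.0151, without IP 1, IP 2 and input 3), immediate early genes (0.0146 and 0.0136, IP 2 and input 3) and ribosomal protein genes (0.0356 and 0.0251, IP 1 and input 2). Between the IPs they were receptors (0.0178, hypothalamus 2) and ribosomal protein genes (0.0011, 0.0467 and 0.0383, without hypothalamus 1, midbrain 2 and midbrain 3). Between the inputs they were ionotropic receptors (0.00914, hypothalamus 1), GABA-A subunits (0.0137 and 0.00473, midbrain 1 and hypothalamus 2), astrocyte markers (0.00196, 0.0388 and 0.0269, without hypothalamus 1, midbrain 2 and midbrain 3) and microglia markers (0.00342 and 0.0424, hypothalamus 1 and midbrain 2). Blood cell and pituitary transcripts (0.0177, 0.0262 and 0.000311, without hypothalamus 1, midbrain 2 and hypothalamus 3) and telencephalic markers (0.000905 and 0.000142, hypothalamus 2 and midbrain 3) were the others there. In the regional difference they were GABAergic markers (0.0328, midbrain IP 2), precursor markers (0.00924, hypothalamus IP 1), thalamic markers (0.0243, test downward, hypothalamus IP 3) and telencephalic markers (0.0253 and 0.00557, hypothalamus input 2 and midbrain input 3). Monoaminergic markers were called without hypothalamus input 1, midbrain input 1, midbrain IP 2 or hypothalamus IP 3 (0.00604 to 0.0207), and endothelial markers without midbrain input 1, hypothalamus IP 2, hypothalamus input 3 or midbrain IP 3 (0.0408 to 0.05). Genes of oxidative phosphorylation were called without hypothalamus IP 1, midbrain input 1, hypothalamus input 2, midbrain IP 2, hypothalamus input 3 or midbrain IP 3 (0.00159 to 0.0492).

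The 10 splits of 6 libraries into groups of 3 are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. It gave 6123 genes in the hypothalamus against at most 0 in another split, 6148 against 0 in the midbrain, 773 against 7 between the IPs, 291 against 0 between the inputs and, with the block by tissue, 98 against 1 for the regional difference.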

Other observations

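The rule behind the genes of the next paragraph was chosen only after the result was seen, as were the values of single libraries that follow.

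Besides the genes named so far, a set of abundant transcripts moved alike in both regions, taken as the genes with at least 20 CPM in the higher group, ranked by the smaller of the regional fold changes. Of 1699 such genes higher in both IPs, those named here were picked from the first 20 by their known roles, which left out others such as Hist1h4d, first in rank (2.12 and 1.84). Cck, the gene for the neuropeptide cholecystokinin, reached log2 fold changes of 2.48 in the hypothalamus and 1.83 in the midbrain. Lhx2, a LIM homeobox factor, reached 1.68 and 2.13, the calcium-binding protein gene Necab2 1.78 and 1.76, and the selenoprotein peroxidase gene Gpx3 1.81 and 1.93. Of 834 genes lower in both IPs, those named were picked from the first 20 by their known cell types. Igf2, a growth factor of meninges and choroid plexus, was at −5.74 and −4.78, Ptgds, the prostaglandin D synthase of meninges and glia, at −4.60 and −4.37, and the radial glia and astrocyte lipid carrier gene Fabp7 at −4.86 and −4.68. The matrix protein gene Sparc was at −5.07 and −4.40.

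Hypothalamus input replicate 2 held the pituitary hormone transcripts Prl at 994 CPM and Gh at 567 CPM, and the IP of the same number held them at 38.5 and 21.4 CPM. The Y-linked gene Ddx3y had 0 or 1 reads in each library of replicate 1 and at least 543 in each library of replicates 2 and 3, where the X-inactivation transcript Xist was also read (5 to 929 reads), so replicate 1 stood apart from the others in Y-linked reads.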
